A study of Mus musculus with 12 samples.

How the data were processed

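Gene expression was measured with Affymetrix arrays in gastrocnemius muscle of 12 male mice, 6 with the mini-muscle phenotype (line 3) and 6 with regular muscle (line 8). Per the labels' protocols, total RNA was extracted with Trizol and column cleanup, and biotinylated cRNA was made from 5 µg of total RNA by the Affymetrix procedure. Per the labels, the left and right muscles of each mini-muscle animal were pooled, whereas the muscle of 1 limb was used from each regular-muscle animal. Each array therefore holds a different animal. Group and line come from the labels, and the replicate numbers only name the arrays.

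The values the authors deposited are linear probe set intensities, made with MAS5 per the submitters' processing notes. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal value on each array separately and then scales each array to a common target. The MAS5 version, its settings, detection calls and scanner files are not given in the sources used here. In the deposited intensities, the mean of each array after leaving out the lowest and highest 2% of probe sets was 800.0, so each array had been scaled to 1 target. All values were above 0. The array medians lay between 211.9 and 275.2 intensity units. Such a scaling fixes the trimmed mean and not the shape of each array's distribution. A group difference in bright transcripts below the highest 2% can therefore shift other transcripts slightly. Arrays have no sequencing depth, and the number of arrays per group limits the precision.

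Of the 45101 probe sets, the platform annotation named a single gene for 34958, several genes for 932 and no gene for 9211. Of the probe sets with a single gene, 34754 were found by gene identifier in a RefSeq gene table (assembly GRCm38.p6), and 0 symbols changed. That table was used for names, chromosomes and gene order, and no coordinates are given. Probe sets of several genes were not named, and those without a gene were tested apart.

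The intensities were taken to log2 without an offset and without further normalization between arrays. For each gene the probe set with the highest mean log2 intensity over all 12 arrays was used (18194 genes), and genes below the median of the gene means (log2 8.56) were left out as dim, which left 9097 genes. Group means were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes below are from limma with Benjamini-Hochberg adjustment unless another test is named. Differences are mini-muscle minus regular-muscle on the log2 scale, with the standard error (SE) of the moderated fit.

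For gene groups, 27 lists written from textbook knowledge were used, covering contractile proteins, metabolism, signalling, housekeeping, other cell types and sampling effects. Of their 623 distinct genes, 567 had a probe set of their own and 496 were above the dim limit. The 26 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list, and fry, a rotation test of whether the genes of a list move on balance in 1 direction, were alternatives. A list score was also computed per array as the mean log2 intensity of the members, each centred on its mean over all arrays, and the group difference was tested with a two-sided exact permutation test over the 924 assignments of 12 arrays to groups of 6 and 6, whose smallest p is 0.0022. Its 95% intervals use the pooled SD of the groups. Array quality values were compared with the same exact test. Called genes were compared between chromosomes with Fisher's exact test.

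The gene lists, the rule for named genes and the alternatives below, except where stated, were chosen before the data were examined. The rule takes the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose groups do not overlap, up to 3 members of each list with the smallest adjusted p, and 14 fixed genes of muscle type, metabolism and growth. Of the fixed genes, Mstn was not analysed here. A gene named outside this rule is marked as chosen after its values were seen.

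The procedure was tested on simulated data for this comparison: among 9097 genes with 200 changed, 61% of those changed 1.5-fold and 91% of those changed 2-fold were called, with 0 errors of sign, and 9 of the 161 calls (5.59%) were unchanged genes. A simulated list shifted by 0.3 was called, and 0 of the 26 other lists were. The simulated noise was drawn independently for each gene. The list result therefore does not show how often camera's preset correlation gives false calls where the genes of a list vary together. No difference in scale between arrays was simulated, and far fewer genes were changed than were called in the data (2426). The rates for single genes therefore need not carry over to those calls.

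The alternatives were quantile normalization, centring of each array on its median, offsets of 16 and 64 before log2, no filter on dim genes, the brightest 33.3% of genes, the mean of all probe sets of a gene, leaving out probe sets of the _s, _x and _a classes (which can match several transcripts), every probe set tested separately, eBayes without the trend or with robust variances, array weights, limma's treat against a 1.2-fold change, a fold of at least 1.5, and leaving out each array in turn. Leaving out the 2 arrays with the highest medians, and using the next brightest probe set of each gene, were chosen after seeing the data. The labels give no batch, scan date or slide, so none was modelled. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.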

Results

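Gene expression was measured on 12 arrays of gastrocnemius, the main calf muscle, each from a different male mouse of lines selected for high voluntary wheel running. They belonged to generation 37 of the selection and were on average 84 days old (79 to 86 days). 6 arrays came from mice of line 3 with the mini-muscle phenotype, an inherited reduction of hindlimb muscle mass, and 6 from mice of line 8 with muscle of regular size. The comparison asks which transcripts differ between the 2 kinds of muscle. Phenotype, line and the pooling of both limbs (mini-muscle) or the use of 1 limb (regular-muscle) divide the arrays in the same way, so a difference below belongs to all 3 together. The values are MAS5 intensities on the log2 scale, and differences are mini-muscle minus regular-muscle, with n = 6 arrays per group throughout.

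Mini-muscle differed from regular muscle across much of the measured transcriptome, with more slow-fibre, fatty acid oxidation, developmental and denervation-associated transcripts and fewer matrix, fibroblast, glycolytic and some fast-fibre transcripts. Camera called 11 of 26 gene lists with its preset correlation and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Fry, which does not compare a list with the other genes, called 14. The glycolytic and fast-fibre calls of camera ended after quantile normalization (camera adjusted p = 0.057 and 0.18). Of 9097 genes tested with limma, 2426 (26.7%) changed, 1356 higher and 1070 lower in mini-muscle. The count was 1543 with the mean of all probe sets of a gene (681 lower) and 1641 with arrays centred on their medians (651 lower). At least 1.5-fold changes were seen in 997 of them (609 higher, 388 lower) and at least 2-fold changes in 274 (168 higher, 106 lower). The 2 groups of arrays did not overlap for 1180 genes, or 13.0%, where chance gives 0.216%. The median difference over all genes was 0.03 and the median SE 0.14. Pearson correlations between arrays of a group were 0.954 to 0.974 and between arrays of different groups 0.924 to 0.948, and no 2 arrays held identical values. The first principal component held 37.1% of the variance and separated the groups, at -22.2 to -17.9 for mini-muscle and 14.8 to 23.9 for regular-muscle arrays.

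The largest increase among called genes whose groups do not overlap was in Sln, which was 24.3-fold higher (log2 4.60, SE 0.36, adjusted p = 7.0e-08). Sln encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump. Ankrd1, a stress-responsive ankyrin repeat protein of the sarcomere, was 21.2-fold higher (log2 4.41, SE 0.26, adjusted p = 2.1e-09). Serpinb1a, an inhibitor of serine proteases, rose by 4.07, Rrad, a small GTPase that restrains calcium channels, by 3.59 (11.50 ± 0.20 against a variable 7.92 ± 2.07), and Myl4, the embryonic and atrial myosin light chain, by 3.34. The other genes among the 10 largest increases were Slc1a1, a glutamate transporter (3.16), Cilp, a matrix protein of cartilage (3.14), Tnfaip2 (3.08), and the partner keratins Krt18 (3.01) and Krt8 (2.99). In the opposite direction, 1700001O22Rik fell by 3.70 (SE 0.37, adjusted p = 8.5e-07), Pla2g7, a phospholipase that inactivates platelet-activating factor, by 3.49, and the 10 largest decreases also held Psmc3ip, a cofactor of meiotic recombination (-3.09). Smox, spermine oxidase, was 6.30-fold lower (log2 -2.66, SE 0.15, adjusted p = 1.5e-09), and Mss51, a mitochondrial protein of skeletal muscle, was 4.21-fold lower (log2 -2.07, SE 0.12). The remaining 5 of the 10 largest decreases were Hmga2-ps1 (-2.59), a pseudogene whose probe set could also take signal from Hmga2, Macir (-2.39), Cbr2, a carbonyl reductase (-2.35), Trnp1 (-1.98) and Tiam1, an activator of the GTPase Rac (-1.98). By the rule that chose these 20 genes, every mini-muscle array lay beyond every regular-muscle array for each, and their ranking holds only among such genes. Of the 20, 14 were read by 1 probe set above the dim limit. Of all genes called and named here, 13 had a group mean below the dim limit of 8.56 (Serpinb1a, Rrad, Slc1a1, 1700001O22Rik, Psmc3ip, Hmga2-ps1, Macir, Trnp1, Tiam1, Ncam1, Hspa2, Junb and Myh3), so that the size and rank of their differences are uncertain. With an offset of 64 added before log2, all 13 kept direction and call with smaller differences, for example -3.03 for 1700001O22Rik.

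Slow-fibre contractile transcripts were higher in mini-muscle, while the change in fast-fibre transcripts was led by a fall of Myh4. Myh7, the slow myosin heavy chain, was 1.98-fold higher (log2 0.99, SE 0.11, adjusted p = 2.9e-06). Slow troponin T, Tnnt1, rose by 0.95 and the slow tropomyosin Tpm3 by 0.75, although its other probe sets above the dim limit gave 0.51, 0.087 and 0.066. Of the 13 measured genes of the slow contractile list, 12 rose and 0 fell, and the count was 12 when adjusted over the list alone. The list score differed by 1.11 (95% interval 0.73 to 1.48). That score is a mean that includes Sln (4.60), and the list median was 0.75. Camera gave adjusted p = 4.7e-08, and adjusted p = 0.34 with an estimated correlation.

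Myh4, the heavy chain of type IIb fibres, was 2.51-fold lower, at 16.04 ± 0.38 (SD) in mini-muscle and 17.37 ± 0.14 in regular muscle (log2 -1.33, SE 0.13, adjusted p = 8.3e-07). Its second, dimmer probe set fell by 3.12. Myoz1, calsarcin of fast fibres, fell by 0.51 and Actn3, the fast-fibre alpha-actinin, by 0.36. The type IIx heavy chain Myh1 rose by 0.29 (adjusted p = 0.0036), at 17.02 ± 0.07 against 16.73 ± 0.15, whereas its second probe set differed by 0.00. These probe sets are of the _x and _a classes, which can match several transcripts. A dim probe set of Myh1 rose by 2.90 (adjusted p = 0.0021 over all probe sets). Its mean of 6.98 lies below the dim limit, too near the floor to decide. The call of Myh1 was lost when arrays were centred on their medians (adjusted p = 0.065). Type IIa Myh2 differed by 0.15 (adjusted p = 0.32), and by 0.26 after quantile normalization (adjusted p = 0.020). Of the 16 genes of the fast contractile list, 8 fell and Myh1 alone rose; adjusted over the list alone, 11 fell and 1 rose. The list was lower (camera adjusted p = 7.4e-04), with adjusted p = 0.52 with an estimated correlation. After quantile normalization this call was lost (adjusted p = 0.18), and the list median moved from -0.21 to -0.03. Over the 71 tested genes with a mean above 16, which include 15 of these 16, the median difference was -0.11 as deposited and 0.01 after quantile normalization.

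**Figure D1:**
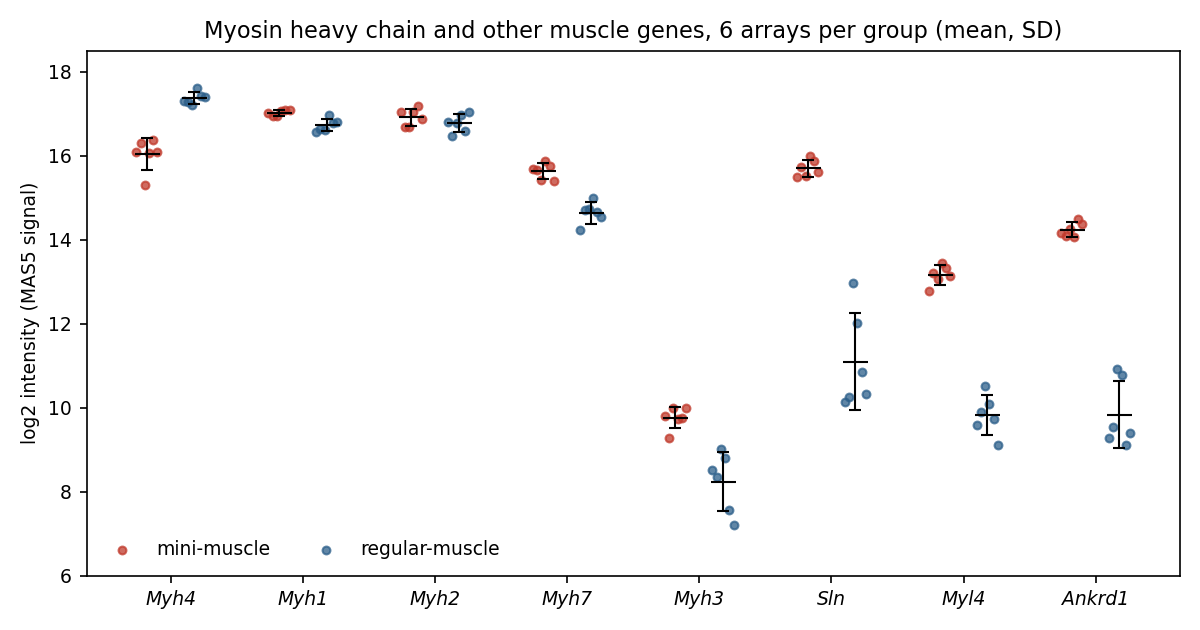
Log2 MAS5 intensity (y axis) of 8 muscle genes (x axis) on each array, with points for the 6 mini-muscle and 6 regular-muscle arrays and bars for mean and SD. Myh4 lay at 16.04 ± 0.38 in mini-muscle against 17.37 ± 0.14 in regular muscle, while Sln lay at 15.70 ± 0.20 against 11.09 ± 1.15.

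Developmental contractile isoforms were higher in mini-muscle. The embryonic heavy chain Myh3 rose by 1.52 (SE 0.27, adjusted p = 3.7e-04) from a low level, at 9.76 ± 0.26 against 8.24 ± 0.71. The neonatal heavy chain Myh8 differed by 0.42 (adjusted p = 0.46). Nes, the intermediate filament nestin, rose by 1.47, although a second probe set of it differed by -0.12. With Myl4 and Ankrd1 above, 6 of the 9 measured genes of the list rose and 0 fell, and 6 rose when adjusted over the list alone. The list median was 1.47 (camera adjusted p = 1.9e-05, and adjusted p = 0.20 with an estimated correlation).

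Transcripts associated with denervation and atrophy also rose. Myog, the myogenic factor myogenin, was 3.98-fold higher (log2 1.99, SE 0.19, adjusted p = 5.6e-07), and the cell adhesion molecule Ncam1 rose by 2.39 (SE 0.35) from a level below the dim limit. Of the 16 genes of that list, 10 rose and 0 fell, and 12 rose when adjusted over the list alone (median 0.76; camera adjusted p = 1.9e-05, and adjusted p = 0.20 with an estimated correlation). The list score was -0.24 and -0.19 on regular-muscle replicates 3 and 4, and -0.72 to -0.59 on the other regular-muscle arrays. At the neuromuscular junction, 3 of 11 genes rose and 0 fell, also 3 when adjusted over the list alone. They were the acetylcholine receptor subunits Chrnb1 (0.84) and Chrna1 (0.72, also in the denervation list) and acetylcholinesterase, Ache (0.40, adjusted p = 0.025, lost in 3 of 12 cases without 1 array). The junction list had a median of 0.29 and camera adjusted p = 0.028, and adjusted p = 0.34 with an estimated correlation. That call was lost without mini-muscle replicate 6 (adjusted p = 0.059) and over the brightest 33.3% of genes (adjusted p = 0.060).

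Myogenic regulators moved both ways. Of 14 measured genes 3 rose and 3 fell, or 5 and 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.71). Besides Myog, Mef2c rose by 0.54, and Eya4, a cofactor of SIX-family homeobox proteins, fell by 0.99.

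Fatty acid uptake and oxidation was the metabolic pathway with the broadest increase. Of its 26 measured genes, 19 rose and 1, the acyl-CoA synthetase Acsl6, fell by 0.34 (named because it was the exception, after its value was seen); adjusted over the list alone, 21 rose and 1 fell. The long-chain acyl-CoA dehydrogenase Acadl rose by 0.87 (SE 0.09, 1.82-fold, adjusted p = 1.9e-06), Pdk4, a kinase that inhibits pyruvate dehydrogenase, by 0.70, and the very-long-chain dehydrogenase Acadvl by 0.67. The list score differed by 0.46 (95% interval 0.28 to 0.65; camera adjusted p = 1.3e-07, and adjusted p = 0.35 with an estimated correlation). It was 0.36 to 0.46 on mini-muscle replicates 1, 3 and 4 and 0.03 to 0.07 on replicates 2, 5 and 6. All regular-muscle arrays lay lower, at -0.28 to -0.18.

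The respiratory chain did not show a comparable rise. Of 72 measured subunits of complexes I to V, 12 rose, 2 fell and 58 did not pass, with the same counts of 12 and 2 when adjusted over the list alone. The median was 0.02 and the list score differed by 0.04 (95% interval -0.06 to 0.15; camera adjusted p = 0.59). After quantile normalization the list passed (adjusted p = 0.022, median 0.08), and it had adjusted p = 0.90 with an estimated correlation. The subunits with the smallest adjusted p were Atp5e (0.39), Ndufv1 (0.33) and Uqcr11 (0.36). In the TCA cycle 6 of 21 enzymes rose and 0 fell, or 6 and 1 when adjusted over the list alone. Idh2, mitochondrial isocitrate dehydrogenase, was 1.92-fold higher (log2 0.94, SE 0.08, adjusted p = 2.6e-07), fumarase (Fh1) rose by 0.53 and Ogdh, of the oxoglutarate dehydrogenase complex, by 0.41. With the mean of all probe sets Ogdh gave -0.70, with a dim second probe set at -1.82. Citrate synthase (Cs) differed by 0.11 (adjusted p = 0.23), whereas 2 dimmer probe sets of it gave 0.22 and 0.41. The TCA list did not pass with camera (adjusted p = 0.13) and passed with quantile normalization (adjusted p = 0.018), without the dim filter (0.038) and with fry (0.025). It had adjusted p = 0.83 with an estimated correlation, and its score passed the exact permutation test (difference 0.13, 95% interval 0.03 to 0.24, adjusted p = 0.036). That score was 0.15 to 0.17 on mini-muscle replicates 1, 3 and 4. On replicates 2, 5 and 6 it was -0.06 to 0.01, overlapping the regular-muscle range of -0.13 to -0.01. Myoglobin, Mb, differed by 0.13 (adjusted p = 0.21), by 0.26 after quantile normalization (adjusted p = 3.5e-04) and by -0.57 with the mean of all probe sets.

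Glycolytic and glycogen-metabolism transcripts were lower. Of 26 genes, 13 fell and 3 rose, or 14 and 3 when adjusted over the list alone. The phosphorylase kinase subunit Phkb fell by 0.95 (SE 0.09, adjusted p = 5.7e-07), the lactate transporter Slc16a3 by 0.997 and the insulin-responsive glucose transporter Slc2a4 by 0.30 (adjusted p = 0.021, lost in 3 of 12 cases without 1 array, and -0.13 at its dimmer probe set). Against the list's direction, muscle glycogen synthase, Gys1, was 2.15-fold higher (log2 1.10, SE 0.09) and hexokinase 2, Hk2, rose by 0.38. The median was -0.22 (camera adjusted p = 0.0021, and adjusted p = 0.41 with an estimated correlation). With quantile normalization the list no longer passed (adjusted p = 0.057, median -0.12).

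Regulators of oxidative metabolism had no common direction. Of 20 genes, 3 rose and 6 fell, or 6 and 6 when adjusted over the list alone. The AMP-activated kinase subunits Prkab2 and Prkaa2 fell by 0.81 (with -1.12 and -0.31 at the dimmer probe sets of Prkab2) and 0.43 and the nuclear receptor Rxrg by 0.93, while the coactivator Ppargc1a differed by 0.06 (adjusted p = 0.80). The list median was 0.08 and its mean -0.04, and camera gave adjusted p = 0.59 with the sign of the mean.

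**Figure D2:**
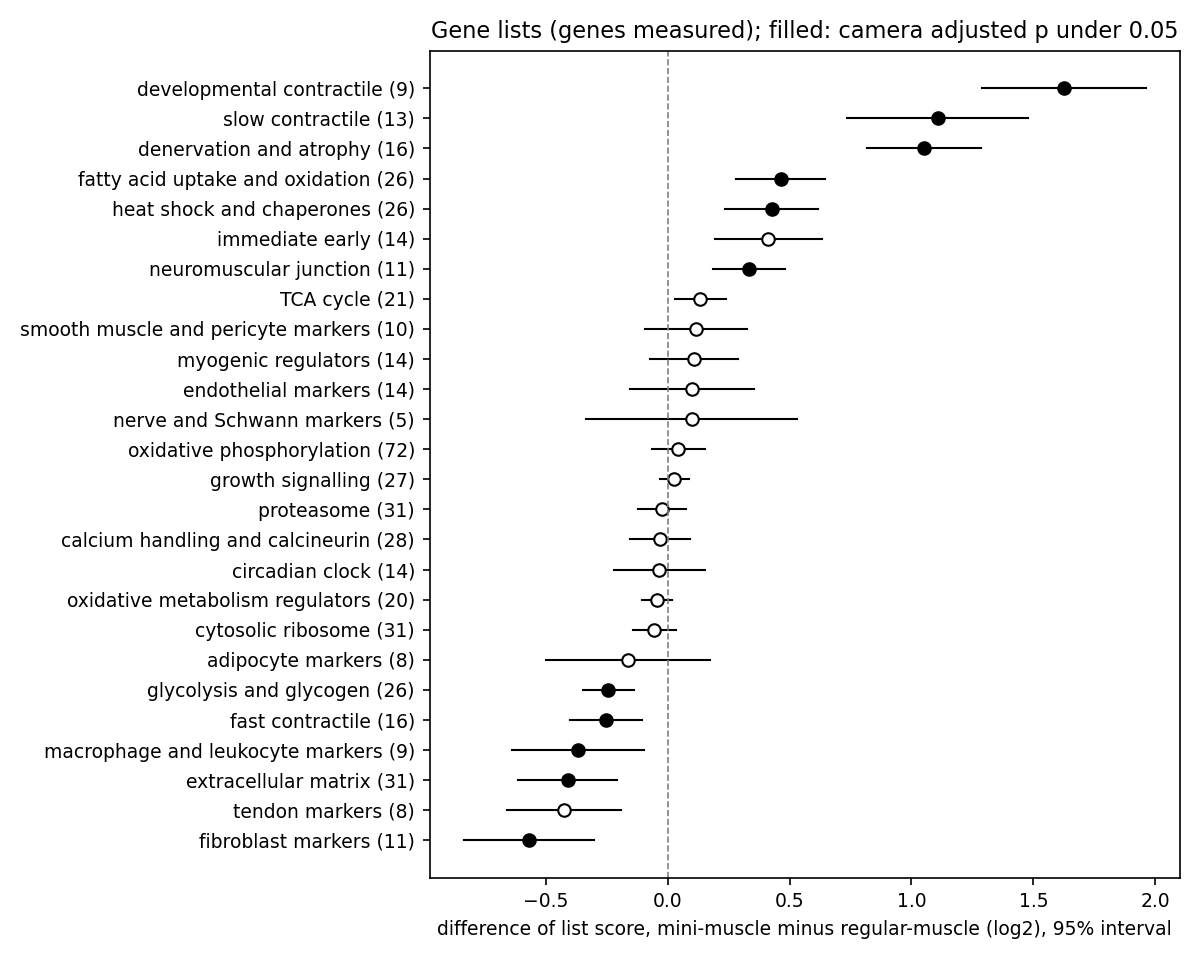
Difference of list score, mini-muscle minus regular-muscle on the log2 scale (x axis), for the 26 tested gene lists with the number of genes measured (y axis). Circles are differences of group means and lines 95% intervals, filled where camera's adjusted p passed 0.05, from developmental contractile at 1.62 to fibroblast markers at -0.57.

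Genes of calcium handling and calcineurin signalling changed in both directions. Of 28 genes, 7 rose and 9 fell, or 9 and 10 when adjusted over the list alone (camera adjusted p = 0.41). Camk2a, a calcium and calmodulin dependent kinase, fell by 1.14, and Jph1, which couples the sarcoplasmic reticulum to the transverse tubules, fell by 0.66, although its second probe set differed by 0.10. In growth signalling 8 of 27 genes rose and 5 fell, also 8 and 5 when adjusted over the list alone (camera adjusted p = 0.91). Igf1, insulin-like growth factor 1, was 3.18-fold lower (log2 -1.67, SE 0.14, adjusted p = 1.1e-07), and its 3 other probe sets above the dim limit gave -1.39, -1.17 and -0.36. Fstl1 fell by 0.86. Akt2 rose by 0.62, while its 2 dimmer probe sets gave 1.24 and -0.066.

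Heat shock proteins and chaperones were higher. Of 26 genes, 14 rose and 2 fell, or 15 and 2 when adjusted over the list alone. Hspa2 rose by 1.68 (SE 0.17), the co-chaperone Bag3 rose by 1.17 and the small heat shock protein Hspb8 by 0.62. The 2 that fell, named after their values were seen, were the endoplasmic reticulum chaperone Hspa5 (-0.31) and the mitochondrial chaperonin Hspe1 (-0.43). The median was 0.30 (camera adjusted p = 3.5e-04, and adjusted p = 0.35 with an estimated correlation).

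Of the housekeeping groups, neither passed as a list. Among 31 proteasome subunits 5 rose and 5 fell, or 6 and 6 when adjusted over the list alone (camera adjusted p = 0.47). Psmd8 (-0.53), Psmd6 (-0.41) and Psmb7 (-0.40) had the smallest adjusted p. Its median was -0.02 as deposited and 0.04 after quantile normalization. Among 31 ribosomal proteins 2 rose and 6 fell, or 2 and 5 when adjusted over the list alone (camera adjusted p = 0.17). Rpsa and Rps19 rose by 0.46 and 0.37 and Rpl4 fell by 0.21. With the mean of all probe sets Rpsa gave -0.29. Adjusted over all single-gene probe sets, dim ones included, Rpl4 did not pass (adjusted p = 0.0505).

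Markers of connective tissue were lower in mini-muscle. Col1a1, a chain of type I collagen, was 2.68-fold lower (log2 -1.42, SE 0.18, adjusted p = 1.4e-05), the matrix proteoglycan Fmod fell by 1.57 and Col1a2 by 1.04. Of 31 genes of the extracellular matrix list, 14 fell and 0 rose, or 15 when adjusted over the list alone (median -0.31; camera adjusted p = 3.5e-05, and adjusted p = 0.34 with an estimated correlation). Fibroblast markers fell as well, 6 of 11 genes with 0 higher, or 9 when adjusted over the list alone. Serpinf1 fell by 0.90, Dcn by 0.85 and Dpt by 0.94. The fibroblast list had a median of -0.64 (camera adjusted p = 3.1e-04, and adjusted p = 0.34 with an estimated correlation). Tendon markers went both ways, 5 of 8 falling and 2 rising, with the same counts when adjusted over the list alone. Comp fell by 0.86 and Thbs4 by 0.74. Camera did not call the tendon list (adjusted p = 0.068, and adjusted p = 0.35 with an estimated correlation), the exact permutation test of its score did (difference -0.42, 95% interval -0.66 to -0.19, adjusted p = 0.014), and fry called it too (adjusted p = 0.0038).

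Macrophage and leukocyte markers were lower in 4 of 9 genes and higher in 0, or lower in 5 when adjusted over the list alone. Mrc1 fell by 0.77 (adjusted p = 0.0036), Csf1r by 0.44 (with -0.56 and 0.047 at its dimmer probe sets) and Lyz2 by 0.64. The list median was -0.44 (camera adjusted p = 0.028, and adjusted p = 0.35 with an estimated correlation), and the call was lost without regular-muscle replicate 3 (adjusted p = 0.059) and over the brightest 33.3% of genes (adjusted p = 0.49). Endothelial markers (1 of 14 called, Pecam1 0.50, adjusted p = 0.044), smooth muscle and pericyte markers (1 of 10, Rgs5 0.23, with 0.03, -0.70 and -0.016 at its other probe sets), nerve and Schwann cell markers (1 of 5, Erbb3 0.44) and adipocyte markers (2 of 8, Fabp4 0.31, with 0.13 and 0.28 at its other probe sets above the dim limit, and Retn -0.55) did not pass as lists, with camera adjusted p of 0.63, 0.52, 0.62 and 0.47. When adjusted over the list alone, 0 endothelial, 1 smooth muscle, 1 nerve and 2 adipocyte markers passed. Adjusted over all single-gene probe sets, dim ones included, several of these genes did not pass. They were Erbb3 (adjusted p = 0.052), Rgs5 (0.058), Lyz2 (0.063), Fabp4 (0.081), Retn (0.087) and Pecam1 (0.10). Without 1 array, the calls of Pecam1, Retn, Fabp4, Lyz2 and Csf1r were lost in 9, 8, 6, 5 and 2 of 12 cases. Of the erythroid list 1 gene was above the dim limit, Hbb-b2, at -0.57 (adjusted p = 0.10).

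**Figure D3:**
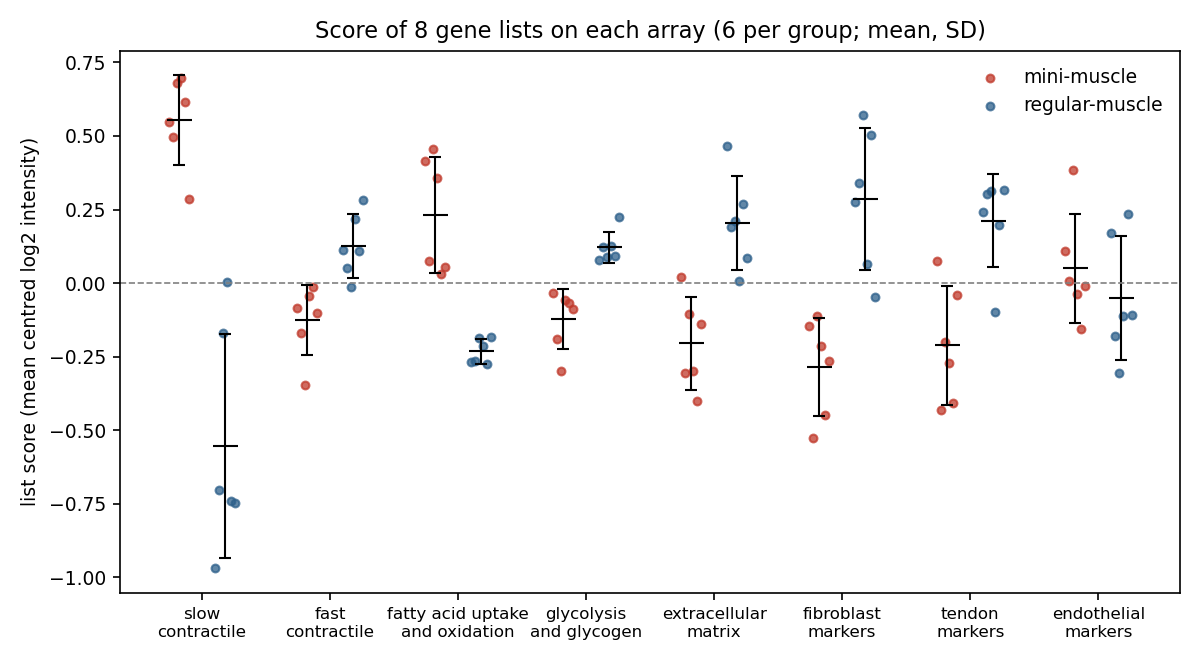
Score of 8 gene lists (x axis) on each array, as the mean centred log2 intensity of the members (y axis), with points for the 6 arrays of each group and bars for mean and SD. The slow contractile score was 0.55 ± 0.15 in mini-muscle and -0.55 ± 0.38 in regular muscle, and the fibroblast score -0.28 ± 0.17 against 0.28 ± 0.24.

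Of the groups that report on sampling, clock genes did not move together. Of 14 genes 1 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.71), among them Bhlhe40 (-0.41), Tef (0.29) and Hlf (-0.59). The list's median was 0.05 and its mean -0.03. Immediate early genes, which respond within minutes to handling, rose in 5 of 14 and fell in 1, or 7 and 1 when adjusted over the list alone. Junb rose from 8.01 ± 1.23, below the dim limit, to 10.01 ± 0.14, Dusp1 rose by 0.82, and Nr4a1 fell by 0.62. The list lay at the edge of the threshold (camera adjusted p = 0.051), with adjusted p = 0.49 with an estimated correlation, and the exact permutation test of its score passed (difference 0.41, 95% interval 0.19 to 0.63, adjusted p = 0.014).

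No value of array quality passed the exact permutation test after adjustment over 6 values, which hold the array median both as intensity and as log2. The signal share of the brightest probe sets and the Gapdh difference passed before adjustment. The highest intensity on each array was not tested. It was 154028 to 174564 in mini-muscle and 183890 to 214669 in regular muscle, without overlap. The median log2 intensity differed by -0.01 (exact permutation p = 0.89) and the interquartile range by 0.06 (exact permutation p = 0.37). The 50 brightest probe sets held 8.95% ± 0.31 of the signal in mini-muscle and 9.61% ± 0.54 in regular muscle (exact permutation p = 0.030, adjusted p = 0.091 over 6 values). The 3' minus 5' difference of the Gapdh control probe sets, which reads RNA and cRNA integrity, was -0.13 ± 0.04 against -0.21 ± 0.04 (exact permutation p = 0.013, adjusted p = 0.078), and that of Actb differed by -0.20 (exact permutation p = 0.24).

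No chromosome carried an excess or deficit of called genes after adjustment by Fisher's exact test, with 2 of 20 at an unadjusted p under 0.05. They were chromosome 17, with 21.8% of 435 tested genes called (Fisher's exact p = 0.020, adjusted p = 0.27), and chromosome X, with 32.8% of 259 (exact p = 0.027, adjusted p = 0.27). On chromosome 11, which holds the skeletal myosin heavy chain cluster, 29.1% of 780 genes were called against 26.4% elsewhere (Fisher's exact p = 0.11, adjusted p = 0.65). With the mean of all probe sets of a gene, chromosomes 16 and 17 passed.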

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

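In this part, the tests of genes with no second probe set, of genes brighter than 16 and of the fast contractile and glycolytic genes after quantile normalization were chosen after the results were seen, and the fibroblast and tendon tests after the list results but before the marker values they use.

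Matrix and fibroblast transcripts were lower in mini-muscle. A lower share of fibroblasts would lower all fibroblast markers, and of the 9 markers outside the matrix list, 1 (Cd34, at 0.07) had a 95% interval wholly above the matrix median of -0.31, where 2 or more would have counted against that explanation. However, 4 of the 9 lay wholly below the matrix median and the marker median was -0.64, so markers and matrix did not fall by 1 common factor and a lower share stays possible without being shown. Whether less tendon was dissected cannot be told apart from a change in the matrix itself, because the score of the 6 tendon markers outside the matrix list differed by -0.18 with a wide 95% interval of -0.43 to 0.07, which includes 0, while the matrix score differed by -0.41. Lower matrix expression per fibroblast, the line of the animals and the pooling of 2 limbs also stay open and were not tested, since the design confounds line and pooling with muscle type.

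The brightest genes differed little: above 16 the median absolute difference was 0.14, against 0.21 to 0.23 in the dimmer ranges. Signal compression near the top of the scanner range did not show over the top 2% of probe sets, where the absolute difference of the second probe set exceeded that of the brightest by a median of 0.031, against 0.017 in genes of middle brightness, a gap of 0.014 (bootstrap 95% interval -0.013 to 0.041). It may act on some genes above 16: where the second probe set was at least 1 log2 unit dimmer, that excess was 0.16, against 0.027 in 643 genes of middle brightness, a gap of 0.13 (0.014 to 0.26), and 13 of 14 genes gave the larger difference there, such as Myh4 with -1.33 and -3.12, though 2 of the 14 (Ryr1 and Cox6c) changed sign. With a smaller gap it was 13 of 23 genes, 5 of which changed sign, and Myh1 went the other way (0.29 and 0.00). A difference in scale between the arrays of the 2 groups was tested as the cause of the lower fast contractile and glycolytic genes. Of the 21 genes already called lower, 90.5% (19) kept the call after quantile normalization. These were 6 of 8 fast and 13 of 13 glycolytic genes, as Myl1 and Tnnt3 lost it. The median of the 21 went from -0.41 to -0.35, so scale alone does not explain most of these called genes. Over all members the list medians went from -0.21 to -0.03 (fast contractile) and from -0.22 to -0.12 (glycolysis), and the list calls ended.

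The genes of largest difference could owe their size to a sequence variant of 1 line under a probe set, since line and muscle type are the same split. The 6 of those 20 genes with another probe set above the dim limit were Ankrd1, Slc1a1, Tnfaip2, Krt8, Psmc3ip and Macir. For them, 100% of 7 other probe sets had the same sign and at least 50% of the difference, which argues against a variant there. However, the dim limit can leave out probe sets that differ. Dim ones of Tnfaip2 (-0.29) and Slc1a1 (1.05) fell short of that criterion, and lie too near the floor to decide. The other 14, among them Sln, Myl4, Smox and Mss51, had no second probe set above the dim limit, so a variant and a change of expression cannot be told apart for them. Of second probe sets below that limit, too near the floor to decide, those of Smox (-2.65, adjusted p = 0.016 over all probe sets) and Serpinb1a (2.09, adjusted p = 0.013) passed in the same direction, while those of Sln (1.999, adjusted p = 0.083), Myl4 (0.10), Trnp1 (0.55) and Tiam1 (-0.29 and 1.03) did not pass. The 2426 changed genes were set against 100 splits of the 12 arrays into 6 and 6, drawn from 462. The real split alone (1 of 100) gave as many, and the highest other gave 29, so a random split seldom gives as many. The other splits mix the 2 groups, which adds the group difference to their spread and lowers their counts. The test cannot tell muscle type from anything else that divides the arrays in the same way.

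Single arrays lay far from the other 5 of their group, by Dixon's test, in 28 of the 250 groups of values examined, where chance gives about 1 in 20 groups, or 12.5. In mini-muscle replicate 3, Myh4 was at 15.31 (others 16.07 to 16.38), Mef2c at 15.13 (15.38 to 15.52), Gys1 at 13.61 (13.79 to 13.90), Phkb at 13.08 (13.50 to 13.65), Pecam1 at 11.03 (10.09 to 10.36) and the immediate early score at -0.16 (0.18 to 0.37). Its array weight was the lowest, at 0.67. In the other mini-muscle arrays, Rxrg was at 10.95 (10.20 to 10.48) and Myh8 at 7.93 (9.33 to 10.08) in replicate 1, Rps19 at 14.05 (14.25 to 14.32) and Myh3 at 9.29 (9.74 to 10.0004) in replicate 2, Camk2a at 11.59 (10.94 to 11.16) and Bhlhe40 at 11.90 (12.33 to 12.58) in replicate 4, and the neuromuscular junction score at 0.36 (0.08 to 0.18) in replicate 6.

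In regular-muscle replicate 4, Cilp was at 13.31 (11.06 to 11.84), Hmga2-ps1 at 11.80 (10.02 to 10.57), Ncam1 at 5.48 (7.48 to 8.08) and the tendon score at -0.098 (0.20 to 0.32). In regular-muscle replicate 3, Cbr2 was at 13.00 (13.89 to 14.23), Chrna1 at 11.32 (10.23 to 10.46), Junb at 5.60 (7.97 to 8.89), the developmental contractile score at -0.18 (-1.14 to -0.81) and the macrophage score at 0.52 (0.03 to 0.20). In the remaining regular-muscle arrays, Tnnt1 was at 13.79 (14.16 to 14.28) in replicate 1, Ppargc1a at 10.38 (10.64 to 10.77) in replicate 2, Rgs5 at 14.61 (14.35 to 14.40) in replicate 5, and Camk2a at 12.76 (12.05 to 12.28), Tef at 13.54 (13.20 to 13.31) and the glycolysis score at 0.22 (0.08 to 0.13) in replicate 6. Dixon's test can miss arrays that stand apart together, as regular-muscle replicates 3 and 4 did in some values, chosen after they were seen. Sln was at 12.97 and 12.03 (others 10.14 to 10.85), Ankrd1 at 10.91 and 10.78 (9.11 to 9.53) and Rrad at 9.72 and 10.37 (4.68 to 8.27). The slow contractile score was -0.17 and 0.004 (-0.97 to -0.70). All of these lay nearer to mini-muscle than the other regular-muscle arrays.

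Probe sets without a named gene also carried a group difference. Of 1145 above the dim limit, 173 (15.1%) passed, 84 higher and 89 lower in mini-muscle, led by 1455773_at (-2.78), 1448484_at (-2.72), 1434025_at (1.84) and 1428301_at (1.77).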

How the results depend on the processing

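Leaving out the 2 arrays of highest median and using the second brightest probe set were chosen after seeing the data. Of the results for named genes under the alternatives, 2222 kept their side of the threshold, 85 lost the call, 6 gained it and 7 reversed. For the list tests 662 kept their side, 21 gained and 17 lost the call. A change of direction between results that did not pass counts as kept. These counts leave out every probe set tested separately, treat and the 1.5-fold limit. Adjusted over all single-gene probe sets, dim ones included, Ache, Erbb3, Fabp4, Lyz2, Pecam1, Retn, Rgs5, Rpl4 and Slc2a4 did not pass (limma adjusted p up to 0.10). No array decided the number of changed genes, which was 2153 to 2396 without each array in turn. It was 2393 after quantile normalization, with 2246 shared, and 2075 without the 2 arrays of highest median, with 1971 shared. It fell to 1543 with the mean of all probe sets of a gene (862 higher, 681 lower; 1314 shared), and by construction to 710 with treat against 1.2-fold (404 higher, 306 lower) and to 997 at 1.5-fold or more (609 higher, 388 lower). Centring arrays on their medians gave 651 lower genes of 1641 in total. The cause was not tested for the mean of all probe sets and for centring, nor for the list and gene results below unless one is given.

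With a correlation estimated for each list, camera called 0 lists (3 at an unadjusted p under 0.05; fry called 14), with adjusted p of 0.337 for slow contractile, 0.522 for fast contractile, 0.199 for developmental contractile, 0.199 for denervation and atrophy, 0.345 for neuromuscular junction, 0.349 for fatty acid oxidation, 0.405 for glycolysis, 0.349 for heat shock, 0.345 for extracellular matrix, 0.345 for fibroblast markers and 0.350 for macrophage markers. The estimated correlations of these 11 lists reached 0.67 (fast contractile), against the preset 0.01, and a higher correlation widens the spread the test allows. Under all other alternatives, the slow contractile, developmental, denervation, fatty acid, heat shock, matrix and fibroblast calls held, with adjusted p up to 0.022. Quantile normalization ended the calls of fast contractile (0.182) and glycolysis (0.0569) and called oxidative phosphorylation (0.0217), the TCA cycle (0.0184) and immediate early genes (0.0485). Over the brightest 33.3% of genes, where fewer members remain, neuromuscular junction (0.0596) and macrophage markers (0.490) lost theirs. The TCA cycle was also called without the dim filter (0.0377) and by fry (0.0245). Tendon markers were called without the dim filter (0.0393), by fry (0.00382), after centring (0.0431), with the mean of all probe sets (0.0218) and without _s, _x and _a probe sets (0.0489). Immediate early genes were called by fry (0.01995), after centring (0.0384), with offsets of 16 (0.0489) and 64 (0.0440), with the mean of all probe sets (0.0368) and with array weights (0.0366).

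Without each array in turn, adjusted p was 0.0112 to 0.0592 for neuromuscular junction (lost without mini-muscle replicate 6), 0.00806 to 0.0593 for macrophage markers (lost without regular-muscle replicate 3), 0.0390 to 0.104 for tendon markers (gained without mini-muscle replicate 1) and 0.0109 to 0.0924 for immediate early genes (gained without mini-muscle replicate 3 or regular-muscle replicate 2, 3 or 6). Of the 12 arrays left out in turn, Pecam1 lost its call for 9, Retn for 8, Fabp4 for 6, Lyz2 for 5, Ache for 3, Slc2a4 for 3 and Csf1r for 2 (adjusted p up to 0.104), and Mb gained one without regular-muscle replicate 4 (0.039). With the mean of all probe sets the sign reversed for Ogdh (-0.70), Rpsa (-0.29), Rgs5 (-0.11) and Mb (-0.57), where Ogdh and Mb each have a dim second probe set, at -1.82 and -1.26. It reversed with the second brightest probe set for Nes (-0.12) and Jph1 (0.10), and without _s, _x and _a probe sets for Akt2 (-0.066). The mean of all probe sets also put 2 chromosomes past the threshold. No paired analysis was possible because the labels share no animal, day or number between the groups. Signal over background limits dim genes, since the deposited values carry no detection calls and the genes below the median level were tested only in the alternative without the dim filter, which called 2199 of 18194 genes.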

Other observations

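The genes in this paragraph and the next are members of the lists and were chosen after their values were seen. Within calcium signalling, the calcineurin subunits Ppp3ca (-0.33), Ppp3cb (-0.59) and Ppp3r1 (-0.62) were lower in mini-muscle, whereas the calcineurin-dependent transcription factor Nfatc2 (0.92) and the calcineurin regulator Rcan2 (0.48) were higher. Camk2d (0.53) rose where Camk2a fell, and the slow-fibre calcium store protein Casq2 rose by 1.38. Sox6, a repressor of slow-fibre genes, was 2.003-fold lower. Among regulators of oxidative metabolism, Esrra (0.70), Ppara (0.45) and Perm1 (0.46) rose, while the glycolytic-fibre AMP-activated kinase subunit Prkag3 fell by 0.72.

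Of the atrophy-associated transcripts, the ubiquitin ligase Fbxo32 rose by 1.04, the cell cycle inhibitor Cdkn1a by 1.55, Gadd45a by 0.87, Hdac4 by 0.72 and metallothionein Mt2 by 1.45, while the ligase Trim63 differed by 0.30 (adjusted p = 0.058). In growth signalling, Mtor (0.38), Rptor (0.54), the myostatin antagonist Fst (0.97), Igfbp3 (0.81) and Igfbp5 (0.68) rose and Smad3 fell by 0.54. In glycolysis, Pfkfb3 (-1.18), Fbp2 (-0.98) and Gpd1 (-0.83) fell, whereas the glycogen branching enzyme Gbe1 rose by 0.54 as did Gys1. Developmental Mybph (2.13) and Tnnt2 (1.43) and the small heat shock protein Hspb7 (1.75) rose.

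The 2 lines were bred apart, so linked differences between them may change genes that lie near each other, and this was tested in 2 places. The test of pairs further apart was added once the adjacent pairs had been seen. Around Myh4, 6 of the 20 tested neighbours were called, 30.0% against 26.7% elsewhere (Fisher's exact p = 0.80), which leaves linkage there undecided with so few genes. Of the 20, 6 have names that start with Myh, and 3 of these were called (Myh3, Myh1 and Myh10).

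Over the genome, 4.39% of 9050 adjacent pairs of tested genes (397) were called in the same direction, against 3.26% to 3.94% after shuffling positions (permutation p = 0.0010), and 4.29% with pairs of similar name left out. Pairs 5 genes apart gave 3.85% (permutation p = 0.081), inside the shuffled range of 3.27% to 3.95%. Pairs 2 apart gave 4.34% (permutation p = 5.0e-04, the smallest possible), 10 apart 4.06% (permutation p = 0.0030) and 20 apart 3.77% (permutation p = 0.18). Pairs called in opposite directions lay below the shuffled range at 1 apart (3.04%, range 3.18% to 3.86%), 2 apart (3.03%, 3.18% to 3.84%) and 5 apart (2.99%, 3.17% to 3.84%). At 10 apart (3.19%) and 20 apart (3.44%) they lay inside it. The adjacent pairs met the criterion for blocks, set before their own result was seen. The pairs 5 apart met one for close neighbours, set after the adjacent pairs had been seen but before their own result. Both criteria used same-direction pairs only. Same-direction pairs 5 and 10 apart give different answers, and opposite-direction pairs 5 apart were fewer than after shuffling. Blocks that differ between the lines and co-regulation of close neighbours therefore cannot be told apart.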
